A study of Mus musculus with 6 samples.

How the data were processed

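RNA levels were compared between pre-BI cells of 3 wild-type (WT) and 3 DKO mice. Per the labels, the animals were female and 8 weeks old, the cells were sorted without culture, and 100 ng of total RNA per sample was labelled with biotin for a whole-transcript Affymetrix array. The design text names 6 separate animals. The deposited table holds 1 value per probe set and array for 20746 probe sets. No unit is stated with it; the deposited values lie in the range of log2 intensities and were used as log2 values, as normalised by the authors. The submitters' processing notes name R 2.10.0. Background correction, summarization, between-array normalization and any filter on probe sets are not given in the sources used here. The means of the arrays lie within 6.74 to 6.76, but their quartiles differ, so the values had not been quantile normalised at this level. No detection calls were available. The number of arrays limits the precision, and no depth applies to array data.

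Probe sets were assigned to genes with the platform annotation of GEO. Of the 20746, 18988 carried 1 gene symbol, 712 carried several and 1046 were not listed in the annotation. For the 11 genes with more than 1 such probe set, the one with the highest mean over all arrays was used, which left 18977 genes. Of these, 18947 had an Entrez identifier that was also found in a RefSeq gene table of the mouse assembly GRCm38.p6. That table was used for this match and for the order of neighbouring genes only. The genome build behind the annotation is not given in the sources used here, so no positions are printed. No gene was left out for a low level.

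DKO was compared with WT in R 4.3.3 with limma 3.58.1, by lmFit and eBayes with neither a trend nor a robust prior, with genotype as the only term. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. All tests are two-sided except where stated. Fold changes, standard errors and 95% confidence intervals come from the same model. The words rose, fell and changed are used for genes past the threshold. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists, and beside it with camera at an estimated correlation and with fry. The pair Hdac1 and Hdac2 was described gene by gene only. Counts adjusted over the list alone use Benjamini-Hochberg within each list. The lists were written from general knowledge of these cells, complexes and pathways.

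The genes to be named followed a rule, though some members without a call that it takes are not named below. It takes Hdac1 and Hdac2, the other genes named in the study's title (Flt3, Ptprf, Pax5 and Tle4), and the 10 largest rises and 10 largest falls among genes past the threshold whose WT and DKO values do not overlap, leaving out predicted or unnamed transcripts. It also takes the 4 members of each list with the smallest p, and, in lists past the threshold in camera, the other members whose value goes against the direction of the list. Members named beyond these, to give every member behind a small count or to fill out a group, and all genes and lists of the closing section that are not in the report, were chosen after their values were seen. The comparison, the lists, the rule and the alternatives below were fixed before the data were examined, except where said otherwise.

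As alternatives, the dimmest 30% of genes were dropped, probe sets of a gene were averaged, all probe sets were tested whether named or not, the arrays were quantile normalised again or median centred, eBayes was run with a trend and a robust prior, array weights were used, the replicate number was added as a block, and each array was left out in turn. Whether replicate numbers pair the arrays was checked by correlating each WT array's deviation from its group mean with each DKO array's. After seeing the narrower range of values in the replicate 2 arrays, the comparison was also run on replicates 1 and 3 only and with a term for replicate 2. Leaving Flt3 and Ptprf out of the genes held low by Pax5 was likewise added after seeing the data. The comparison was repeated for all 10 divisions of the 6 arrays into groups of 3.

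The procedure was tested on simulated data with 20 runs of 18977 genes and 200 changed genes per run. It recovered 89.0% of changes of 0.5 on the log2 scale, 99.9% of changes of 1 and 100% of changes of 2, and on average 6.42% of all calls were false. A shifted list was called in 20 of 20 runs, also with an estimated correlation, and unshifted lists were called in 0% of tests; simulated genes were independent, which real genes are not.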

Results

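RNA from sorted mouse pre-BI cells was hybridised to whole-transcript Affymetrix arrays, and the level of each transcript was given as a log2 value per array. Pre-BI cells are an early committed stage of B-cell development in the bone marrow. The cells had been taken directly from female mice 8 weeks old and sorted as positive for B220, CD19 and c-Kit and negative for CD25 and IgM. There were 3 wild-type (WT) animals and 3 animals labelled DKO, each animal giving 1 array. The labels do not spell out DKO. The study's title names HDAC1 and HDAC2, a pair of closely related class I histone deacetylases, and concerns their part, with the B-lineage factor Pax5, in keeping certain genes low in B cells. The number of arrays, 3 per genotype, limits the precision of every value below. Mean values per array lay between 6.74 and 6.76. The interquartile range was narrower in replicate 2 of both genotypes, at 1.96 (WT) and 2.01 (DKO), than in the other 4 arrays, at 2.14 to 2.29. Arrays of 1 genotype correlated at 0.991 to 0.996 across genes and arrays of different genotypes at 0.968 to 0.980. Genes are not independent replicates, so these correlations only describe the arrays.

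Hdac1 and Hdac2 were both strongly reduced in every DKO array. Hdac1 fell 5.34-fold (95% confidence interval 4.41 to 6.47), from a log2 level of 10.17 ± 0.17 in WT to 7.76 ± 0.23 in DKO (SD, n = 3 each), with an adjusted p of 8.18e-06. Hdac2 fell 6.82-fold (5.89 to 7.91), from 10.23 ± 0.13 to 7.46 ± 0.13, with an adjusted p of 1.57e-06. The WT values were 10.33, 9.996 and 10.20 for Hdac1 and 10.31, 10.08 and 10.31 for Hdac2. The DKO values were 7.87, 7.91 and 7.50 for Hdac1 and 7.61, 7.40 and 7.37 for Hdac2. In all 6 arrays the levels of both genes went with the genotype label. The DKO levels still lay above 5.68, the upper bound of the lowest 3 deciles of genes by level. Whether the probes lie in the deleted part of either gene is not given in the sources used here, so the size of the fall is not a measure of deletion.

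The other genes named in the title also differed. Flt3, a receptor tyrosine kinase of multipotent and early lymphoid progenitors, rose 2.32-fold (1.92 to 2.80), from 7.46 ± 0.25 to 8.67 ± 0.12 (SD, n = 3 each), with an adjusted p of 1.86e-04. Ptprf, a receptor-type tyrosine phosphatase, rose 1.67-fold (1.47 to 1.91), from 6.43 ± 0.13 to 7.17 ± 0.064, with an adjusted p of 3.51e-04. Pax5, the transcription factor of B-lineage commitment, fell 1.32-fold (1.16 to 1.50), from 10.07 ± 0.091 to 9.67 ± 0.094, with an adjusted p of 0.0071. Tle4, which encodes the Groucho corepressor also called Grg4, fell 1.49-fold (1.32 to 1.68), from 8.25 ± 0.096 to 7.67 ± 0.048, with an adjusted p of 7.10e-04. For each of these 4 genes, all 3 DKO values lay on one side of all 3 WT values. The title chose these genes, so they are not independent evidence of a direction.

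**Figure D1:**
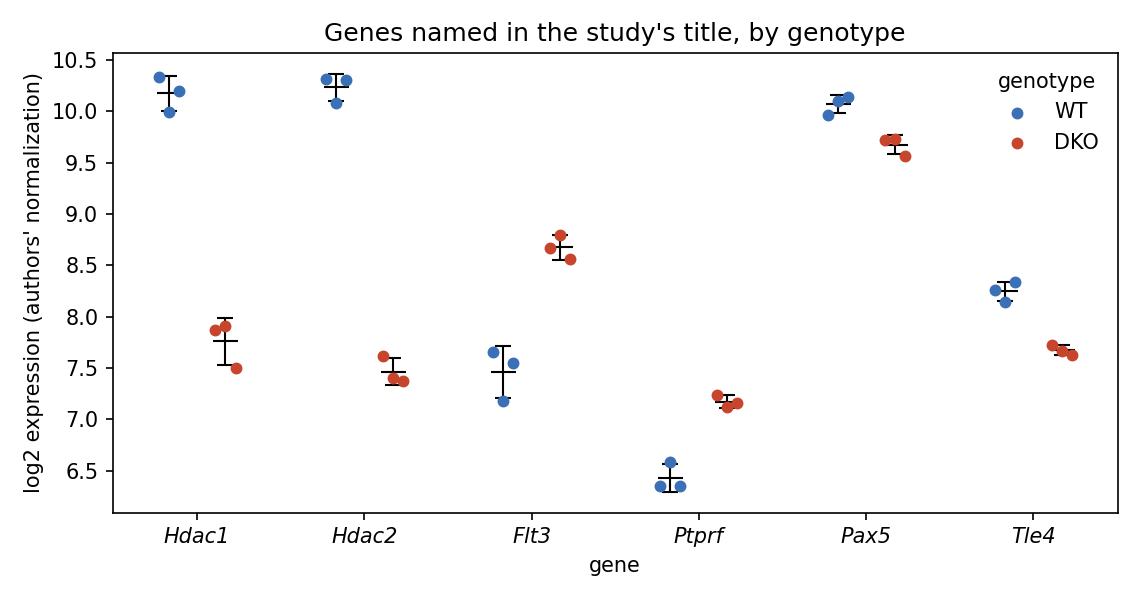
Log2 expression (vertical axis, as normalised by the authors) of the 6 genes named in the study's title, with a point per array, a short bar at the mean of each genotype and error bars of 1 SD (n = 3). Hdac1 and Hdac2 sat above 9.9 in every WT array and below 8.0 in every DKO array, Flt3 and Ptprf were higher in DKO, and Pax5 and Tle4 were lower.

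The largest rises were Crip2, a LIM-domain protein (4.01-fold, 95% confidence interval 3.19 to 5.04), Ppp2r5c, a regulatory subunit of the phosphatase PP2A (3.92-fold, 3.41 to 4.50), and Rangrf, a regulator of the nuclear transport GTPase Ran (3.64-fold, 3.11 to 4.26). They were followed by Dkkl1 (3.57-fold), the lysosomal protease gene Ctsl (3.37-fold), Rcn3 (3.37-fold), Lactb (3.30-fold), Ifitm1 (3.23-fold), Bex1 (3.17-fold) and the glutathione transferase gene Gstm5 (3.07-fold). Beside Hdac1 and Hdac2, the largest falls were Ifi209, an interferon-inducible gene (5.76-fold, 4.25 to 7.81), the metalloreductase gene Steap4 (4.99-fold) and Ifi214 (4.44-fold, 3.27 to 6.04). Ifi209 and Ifi214 belong to a family of closely similar genes, and whether their probes are specific to each was not checked. Next came Cacna2d1 (3.82-fold), Grb7 (3.82-fold), Ifi44l (3.74-fold), Enpep, the aminopeptidase of the early B-cell surface antigen BP-1 (3.70-fold), and Cdc25b, a phosphatase that activates cyclin-dependent kinases (3.69-fold). Adjusted p-values of these genes, 10 per direction, ran from 1.57e-06 (Hdac2) to 0.0021 (Ifi44l), and the WT and DKO values of each did not overlap. The folds of Gstm5 (WT mean 5.66), Cacna2d1 (DKO mean 5.35) and Steap4 (DKO mean 5.94) are at least the values given, since one of their means lies where signal cannot be told from background, so their places in these rankings are lowest ones. Predicted or unnamed transcripts were skipped in this choice, 0 among the rises and 2 among the falls.

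In all, 3669 of 18977 tested genes (19.3%) changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 2223 of them higher and 1446 lower in DKO. At least 2-fold changes were seen in 115 genes that rose and 88 that fell. WT and DKO values did not overlap for 32.7% of all genes, where chance gives 10%. Changes were rare at low levels: 0.913% of the genes in the lowest 3 deciles passed the test, against 27.2% of the others. Detection calls are not given in the sources used here, so levels around 5 to 6 cannot be told from background, and folds against such a level are written as "at least". The number of genes called higher in DKO was 1448 without DKO replicate 1 and 1465 after median centring of the arrays, against 2223.

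**Figure D2:**
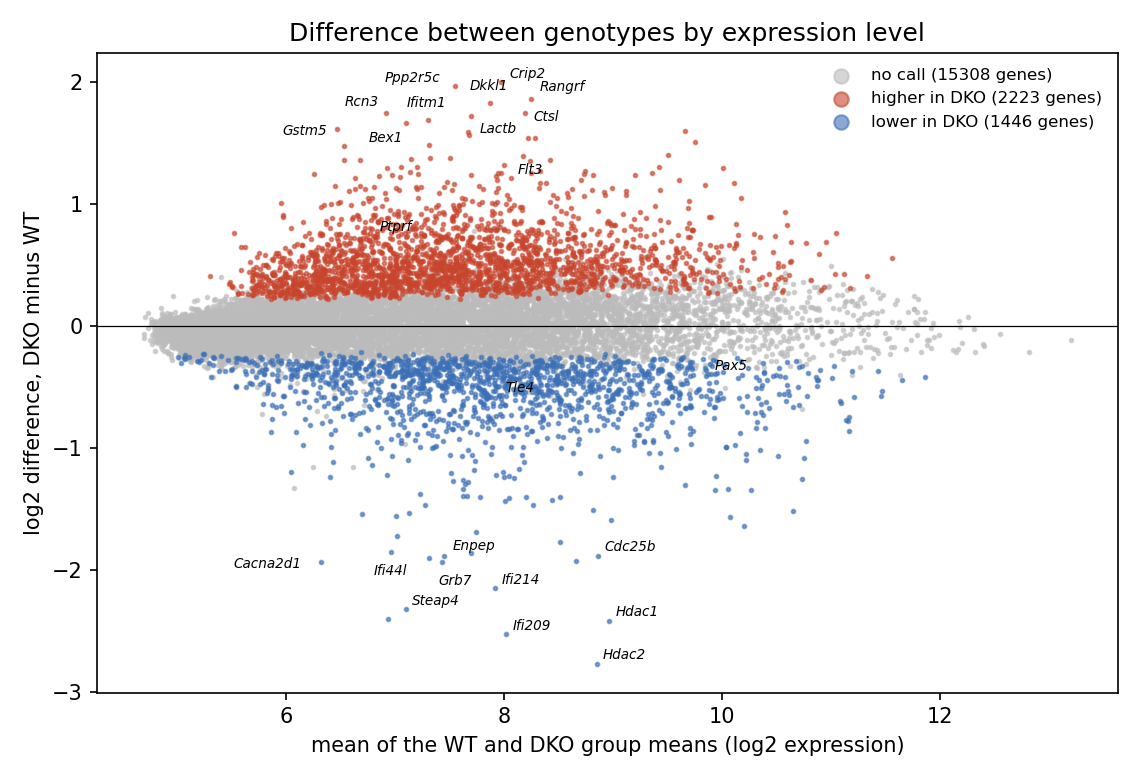
Log2 difference, DKO minus WT (vertical axis), against the mean of the genotype means on the log2 scale (horizontal axis), with a point per gene. Red points are the 2223 genes higher in DKO, blue points the 1446 lower and grey points those with no call; the genes with the largest changes and those of the title are labelled, and Hdac2 and Ifi209 lie lowest.

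Genes of early B-cell identity fell together. Of 28 measured members of the list of early B-cell identity and the pre-B-cell receptor (pre-BCR), 23 fell, 1 rose and 4 did not pass the test, with a median log2 difference of -0.59; the counts were the same when adjusted over the list alone. Vpreb3 fell 2.86-fold, Bst1 2.64-fold, Cd79a, a signalling chain of the B-cell receptor, 2.12-fold, and the transcription factor gene Lef1 2.02-fold. Rag1 and Rag2, the recombinase genes of antigen receptor assembly, fell 2.54-fold and 2.08-fold, Ebf1 1.40-fold and Il7r 1.48-fold (these 4 were picked after their values were seen). Bcl11a rose 1.36-fold, a call that was lost without DKO replicate 1 (adjusted p = 0.060). The 4 members without a call were Igll1 (-0.21 on the log2 scale, a fall past the test without WT replicate 2, at an adjusted p of 0.039), Kit (0.048), Cd24a (0.036) and Spi1 (-0.029); the c-Kit protein was one of the sort markers. Of 19 measured genes that Pax5 is known to raise, 13 fell, 0 rose and 6 did not pass, both over all genes and adjusted over the list alone, with a median of -0.65. The 0 comes from limma, and 13 of the 19 had an unadjusted p under 0.05. Besides Vpreb3, Lef1 and Bst1, the members that fell included Spib (2.65-fold lower), a transcription factor gene of B and plasmacytoid dendritic cells, while Cd72 (0.18) and Irf8 (0.10) had positive differences without a call. Both lists shifted down in camera (adjusted p = 6.27e-15 and 1.78e-11), but neither with an estimated correlation (adjusted p = 0.24 for both); they share 6 genes and are not independent. Vpreb1 and Vpreb2, which are near-identical copies, both fell, and Cd19 was not among the genes measured.

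Markers of other lineages moved unevenly. Of all tested genes 19.3% changed, and 27.2% of those above the lowest 3 deciles by level. A count of changed members near these shares does not set a list apart. Of 18 measured genes that Pax5 is known to hold low, 4 rose, 0 fell and 14 did not pass, with the same counts adjusted over the list alone and a median of 0.15. Jchain, the joining chain gene of secreted antibodies, had a log2 difference of -0.70 with an adjusted p of 0.30, from DKO values of 5.34, 5.30 and 7.18, of which the first 2 cannot be told from background. Without DKO replicate 3 it fell by at least 1.31 on the log2 scale (adjusted p = 1.06e-04). Notch1 had a difference of -0.23, which passed as a fall with a term for replicate 2 (adjusted p = 0.039), and Prdm1 one of -0.086. The means of Prdm1, 5.62 in WT and 5.53 in DKO, cannot be told from background. Those that rose were Flt3, Ptprf, Xbp1 (1.52-fold), a transcription factor gene of plasma cells, and the chemokine receptor gene Ccr2 (1.39-fold). In limma, 7 of the 18 had an unadjusted p under 0.05. Camera put the list up (adjusted p = 0.028, and adjusted p = 0.41 with an estimated correlation). The title names Flt3 and Ptprf, so they are no independent evidence of the list's direction; without them the adjusted p was 0.16, with 2 of 16 members risen. The list's call was also lost without WT replicate 3, DKO replicate 1 or DKO replicate 2 (adjusted p of 0.053, 0.055 and 0.071), with the dimmest genes dropped (0.11) and after another quantile normalization (0.080). Without DKO replicate 1, 2 members rose and the adjusted p of Xbp1 was 0.066, as it was 0.060 after median centring; that of Ccr2 was 0.064 to 0.097 without WT replicate 3, DKO replicate 1 or DKO replicate 2.

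Among stem and multipotent progenitor genes, 6 of 19 rose and 1 fell, with the same counts adjusted over the list alone and a median of 0.11. Besides Flt3, Hoxa9 (1.66-fold) and Meis1 (1.35-fold), homeobox genes of stem and progenitor cells, rose, and Slamf1, a surface receptor gene of stem cells, fell at least 1.55-fold (DKO mean 5.47). The list did not pass in camera (adjusted p = 0.058; adjusted p = 0.41 with an estimated correlation) but did in fry (FDR 0.013). The other members that rose were Bcl11a, Satb1 and Eng, whose calls were lost without DKO replicate 1 (adjusted p of 0.060, 0.10 and 0.13), where 3 members rose. The call of Satb1 was also lost without WT replicate 1 or DKO replicate 2 and that of Eng without WT replicate 2 or 3 or DKO replicate 3. The list passed in camera without WT replicate 3 (adjusted p of 0.049) and after median centring (0.047).

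Markers of other blood cell types also moved in both directions, in cells sorted for B220, CD19 and c-Kit. Their counts stand against a changed share of 19.3% among all tested genes and 27.2% above the lowest 3 deciles. Of 26 markers of T, NK and innate lymphoid cells, 6 rose and 2 fell, or 7 and 2 adjusted over the list alone, with a median of 0.061. The risen members included genes of cytotoxic lymphocytes: Nkg7 went from 7.38 to 8.17 (1.74-fold), Gzma from 6.30 to 7.15 (1.81-fold) and Ccl5 from 8.19 to 8.81 (1.53-fold). The others were Klrd1, Il2rb and Zap70, whose calls were lost in 4, 2 and 1 of the 6 fits that leave out 1 array. Ncr1, an NK-cell receptor gene, had a log2 difference of 0.60 without a call. It rose with the dimmest genes dropped (adjusted p = 0.034), without WT replicate 2 (0.0018) and with the replicate number as a block (0.0024). Lat, a T-cell receptor adaptor gene, fell 1.49-fold, and Cd5 fell at least 1.21-fold (DKO mean 5.81), with an adjusted p of 0.056 to 0.079 without WT replicate 1 or 2 or DKO replicate 1 or 3. Cd3e, of the T-cell receptor complex, had a log2 difference of 0.036 with an adjusted p of 0.82. The list did not pass in camera (adjusted p = 0.058; adjusted p = 0.79 with an estimated correlation) or in fry (FDR 0.31). It passed in camera without WT replicate 2 (adjusted p = 0.0023), without DKO replicate 3 (0.0052), in replicates 1 and 3 only (0.026), with a term for replicate 2 (0.043), after median centring (0.025) and with array weights (0.036), and 3 members rose without DKO replicate 1.

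Among 13 markers of plasmacytoid dendritic cells, 3 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.27; adjusted p = 0.77 with an estimated correlation). Ly6d, which also marks lymphoid progenitors biased to the B lineage, rose 2.84-fold, while Spib and Tcf4 (1.31-fold) fell. Bst2 rose 1.67-fold, with an adjusted p of 0.053 without DKO replicate 3, and Cox6a2 rose 1.29-fold, with an adjusted p of 0.061 to 0.12 without WT replicate 2 or 3 or DKO replicate 1 or 2. After median centring 1 of these markers rose. Of 24 myeloid markers, Tyrobp rose (1.34-fold) and Lyz2 (1.41-fold), Itgam (1.39-fold) and Csf2ra (1.29-fold) fell, and the counts adjusted over the list alone were the same (camera adjusted p = 0.47). Each of these 4 calls was lost in at least 2 of the 6 fits that leave out 1 array, with adjusted p-values of up to 0.094. Without WT replicate 3 no myeloid marker passed, without DKO replicate 1 Tyrobp did not, and without DKO replicate 3 only 1 marker fell. Of 15 erythroid and megakaryocyte markers, limma called 0 in either direction, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.11; fry FDR 0.40). The differences of the members reached down to -1.33 on the log2 scale without a call, with a mean of -0.24 and a median of -0.13. Alas2, of haem synthesis, had a log2 difference of -0.29 with an adjusted p of 0.099. Without WT replicate 1 it fell (adjusted p = 0.018) and the list's adjusted p was 0.029, and without WT replicate 3 that of the list was 0.049. Alas2 also fell after another quantile normalization (adjusted p = 0.042), with the replicate number as a block (0.031) and with a term for replicate 2 (0.024).

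Most genes of mitosis fell, and a smaller part of the genes of DNA replication rose. Of 29 measured genes of G2/M and mitosis, 22 fell, 0 rose and 7 did not pass, with a median log2 difference of -0.47; adjusted over the list alone, 27 fell. Cenpe, a kinetochore motor, fell 1.64-fold, Cenpf 1.64-fold, Kif11, a spindle motor, 1.59-fold and Ect2, a regulator of cytokinesis, 1.58-fold. The 0 comes from limma, and 27 members had an unadjusted p under 0.05. The list shifted down in camera (adjusted p = 3.47e-15; adjusted p = 0.41 with an estimated correlation; fry FDR 0.011). Of 33 genes of DNA replication and G1/S, 9 rose, 1 fell and 23 did not pass, with a median of 0.20; adjusted over the list alone, 10 rose and 3 fell. Ccnd2, a D-type cyclin, rose 1.92-fold, Chaf1b, a histone chaperone subunit of replicating chromatin, 1.92-fold and E2f1, a transcription factor of S-phase genes, 1.50-fold, while E2f2 fell 1.52-fold. Differences below 0 without a call were seen for Uhrf1 (-0.27), Rrm1 (-0.26), Tyms (-0.25), Rrm2 (-0.22), Ccnd3 (-0.14), Pcna (-0.12), Pola1, Ccne2, Slbp and Pole (-0.080 to -0.012). With a term for replicate 2, Uhrf1, Rrm1, Tyms and Rrm2 fell (adjusted p of 0.0058, 0.0096, 0.029 and 0.038), and of the whole list 16 members rose and 5 fell. The list shifted up in camera (adjusted p = 0.028; adjusted p = 0.83 with an estimated correlation) but not in fry (FDR 0.40). Its call was lost without WT replicate 2 (0.40, with 4 members fallen, Rrm1, Uhrf1 and Rrm2 among them), and without DKO replicate 1 (0.080) or DKO replicate 3 (0.078), where 5 members rose. It was also lost with the dimmest genes dropped (0.14) and in replicates 1 and 3 only (0.055, with 4 members fallen). After median centring 5 members rose, and after another quantile normalization 13 rose and 5 fell, the list keeping its call in both. Among 6 inhibitors of cyclin-dependent kinases, Cdkn2c (1.86-fold), Cdkn2d (1.66-fold) and Cdkn1b (1.64-fold) fell and 0 rose, also adjusted over the list alone, and Cdkn1c had a log2 difference of 0.17. In limma, 3 of these 6 had an unadjusted p under 0.05. The list did not pass in camera (adjusted p = 0.074; adjusted p = 0.41 with an estimated correlation), though it did without WT replicate 2 (0.049) or DKO replicate 3 (0.027), after another quantile normalization (0.039) and in fry (FDR 0.017). The probe set of Cdkn1a carries another symbol as well, so it was not among the named genes tested. Its value in the fit of all probe sets is not given here.

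In the lists of interferon-stimulated and histone genes, most of the changed members fell. Of the interferon-inducible genes outside the list that were named above, Ifitm1 rose 3.23-fold, while Ifi209, Ifi214 and Ifi44l fell. Of 21 interferon-stimulated genes, 11 fell, 1 rose and 9 did not pass, with a median of -0.28; adjusted over the list alone, 16 fell and 1 rose. Ifit2 fell 1.79-fold, Ifi27l2a 1.65-fold, Rtp4 1.45-fold and Ifih1, a sensor of viral RNA, 1.24-fold, while Bst2, which tethers virus particles to the cell surface, rose 1.67-fold, and Mx1 had a difference of 0.14 without a call. The means of Mx1, 5.38 in WT and 5.53 in DKO, cannot be told from background. The list shifted down in camera (adjusted p = 4.93e-06; adjusted p = 0.41 with an estimated correlation). Without WT replicate 3, DKO replicate 1 or DKO replicate 3, 5, 5 and 3 members fell, and Rtp4, Ifih1 and Bst2 lost their calls in 1 or 2 of these fits, at adjusted p-values of 0.053 to 0.060; Bst2 also did after median centring (0.062). Of 13 histone genes, H2ax (1.72-fold), which marks DNA breaks when phosphorylated, the linker histone genes H1f2 (1.71-fold) and H1f3 (1.26-fold) fell and H2aj (1.24-fold) rose; adjusted over the list alone, 4 fell and 1 rose, with a median of -0.24. That list shifted down in camera as well (adjusted p = 0.011; adjusted p = 0.44 with an estimated correlation), but not without DKO replicate 2 (0.072), nor in fry (FDR 0.082). Without DKO replicate 3, 5 histone genes fell, and without WT replicate 3 H1f3 (0.059) and H2aj (0.058) lost their calls. After another quantile normalization 5 fell and H2aj lost its call (0.078).

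Genes of the p53 response and apoptosis went both ways, 9 of 25 rising and 6 falling, or 9 and 7 adjusted over the list alone (camera adjusted p = 0.35). Bcl2l11, a pro-apoptotic BH3-only gene also called Bim, rose 1.66-fold, the death receptor gene Tnfrsf10b at least 1.64-fold (WT mean 5.87) and Aen 1.44-fold, while Trp53inp1 fell 1.99-fold. The anti-apoptotic genes Bcl2l1 and Mcl1, picked after their values were seen, fell 1.50-fold and 1.35-fold. In the fits without DKO replicate 1 or DKO replicate 3 and after median centring, 5 members rose. Of 24 immediate early and stress genes, 3 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.80). Hsph1, a heat-shock protein gene, rose 2.23-fold, Ier2 1.53-fold and Ier3 at least 1.25-fold (WT mean 5.56). Jun fell 1.99-fold, Btg2 1.78-fold, Zfp36, which promotes mRNA decay, 1.65-fold, Klf6 1.35-fold and Dusp1 1.33-fold. Dusp1 lost its call without WT replicate 2 or 3 or DKO replicate 2 or 3 (adjusted p of 0.10 to 0.13).

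Other histone deacetylases and members of class I deacetylase complexes also went both ways. Of 27 measured members, 5 rose and 5 fell, or 5 and 6 adjusted over the list alone, with a median of -0.011 (camera adjusted p = 0.69). Hdac8 fell 1.82-fold, Hdac7 1.78-fold, Tbl1xr1, of the NCoR complex, 1.53-fold, Hdac5 1.42-fold and Mta2, of the NuRD complex, 1.33-fold. Rcor2, of the CoREST family, rose 1.68-fold, Gatad2a 1.44-fold, Sap30 1.38-fold, Hdac6 1.30-fold and Sin3a 1.25-fold. Without DKO replicate 1 or DKO replicate 3 and after median centring, 3 members rose, Hdac6 having an adjusted p of 0.053 to 0.075 and Sin3a one of up to 0.10 there, as well as without WT replicate 1 or 2 and with a trend and robust prior. Mta2 had an adjusted p of 0.051 without WT replicate 3. Of the 6 Groucho corepressor genes, Tle4 alone changed, also adjusted over the list alone (camera adjusted p = 0.44). Tle5 had a log2 difference of 0.23 and Tle6 one of -0.22, with adjusted p-values of 0.25 and 0.10, and without DKO replicate 2 Tle5 rose (0.37 on the log2 scale, adjusted p = 0.010). After another quantile normalization Tle6 fell (adjusted p = 0.033).

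Few genes of the remaining lists changed. Of 18 genes of later B-cell stages, Ltb, a lymphotoxin gene, rose 1.92-fold and Cd74, the invariant chain of MHC class II, 1.75-fold, also adjusted over the list alone, with camera at an adjusted p of 0.80. The list's median was -0.093 and its mean 0.077. Cd74 had an adjusted p of 0.055 to 0.068 without WT replicate 1, DKO replicate 1 or DKO replicate 2, where 1 member rose, and 5 members rose without WT replicate 3. H2-Aa had a log2 difference of 0.54 without a call (adjusted p = 0.12). It rose without WT replicate 3 (adjusted p = 0.0047), with the replicate number as a block (0.049) and with a term for replicate 2 (0.045). Il2ra had a difference of -0.21 without a call and fell in the latter 2 fits (0.047 and 0.030), with a DKO mean of 5.18. Of 24 neuronal genes, Bex1 (3.17-fold) and Bex2 (at least 2.01-fold, WT mean 5.44) rose, also adjusted over the list alone (camera adjusted p = 0.90), and the list's median was -0.035 and its mean 0.087. In WT, 10 of these genes had a mean above 5.68, so a fall of the others would not be seen. Of 19 imprinted genes, Igf2r (1.66-fold) and Peg3 (at least 1.34-fold, WT mean 5.69) rose, also adjusted over the list alone (camera adjusted p = 0.16), and 4 did without WT replicate 2, with the dimmest genes dropped, with array weights and with a trend and robust prior. Of 23 ribosomal protein genes, Rpl14 (1.27-fold), Rpl22 (1.26-fold) and Rpl7a (1.25-fold) rose, and 0 did when adjusted over the list alone, where 4 had an unadjusted p under 0.05 in limma (camera adjusted p = 0.075; fry FDR 0.40). None of the ribosomal protein genes rose without WT replicate 2, WT replicate 3 or DKO replicate 3, nor after median centring (list adjusted p = 0.096) or with a trend and robust prior, and 1 did without DKO replicate 1, while the list passed in camera without WT replicate 1 (0.0092) or DKO replicate 2 (0.039) and after another quantile normalization (0.015). Of 22 germ-cell genes, limma called 0, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.69; fry FDR 0.57). Of these, 3 had a WT mean above 5.68, so a fall of the others would not be seen. Stag3, a meiotic cohesin gene, had a log2 difference of 0.23.

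Among the 22 lists tested, 7 passed in camera with its preset correlation, 2 shifted up and 5 down. With an estimated correlation 0 of the lists passed, 2 having an unadjusted p under 0.05, and in fry, which asks whether a list's genes move one way on balance, 7 did. The lists that passed in fry were not the same 7. The stem cell and kinase inhibitor lists passed in fry and not in camera. Among the 7 of camera with its preset correlation, the replication and histone lists did not pass in fry. For these 7 lists the estimated correlations ran from 0.039 (genes held low by Pax5) to 0.71 (replication), above the preset 0.01. Camera's adjusted p-values are therefore not read as strength of evidence. Other divisions of the 6 arrays into groups of 3 put up to 12 lists past the camera threshold. Those divisions mix the genotypes on both sides and keep part of their difference, so they do not show what chance alone would give. The counts of members that passed limma's test do not rest on camera.

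**Figure D3:**
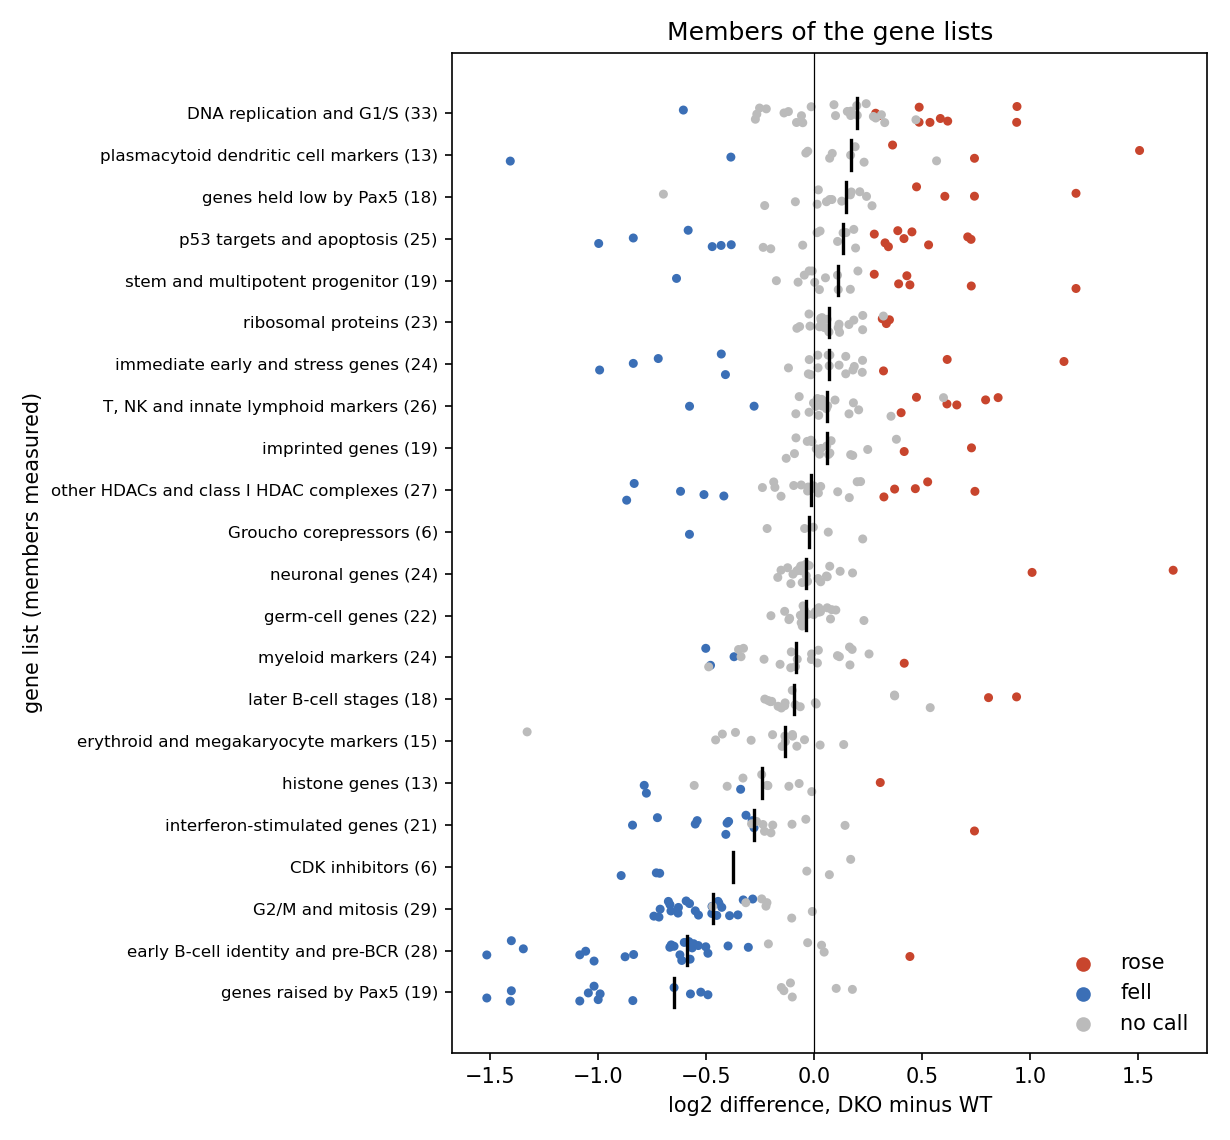
Log2 difference, DKO minus WT (horizontal axis), of each measured member of the 22 gene lists (vertical axis, members measured in brackets), with red points for members that rose, blue for those that fell, grey for those with no call and a black bar at each list's median. Most members of the early B-cell, Pax5-raised and G2/M lists lie left of 0.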

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

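The tests of NK markers outside the fixed lists, of replicates 1 and 3 only for the T and NK list, and of the spread among B-lineage genes were chosen only after the result was seen. Probe sets outside the comparison of named genes also passed the threshold of 0.05. Of those not listed in the annotation, 105 were higher and 77 lower in DKO. Of those with several gene symbols, 40 were higher and 37 lower.

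Of the 26 T, NK and innate lymphoid markers, 6 rose in DKO and 2 fell, although the sort required CD19, B220 and c-Kit. Above the lowest 3 deciles, 27.2% of all genes changed, so the number of changed markers alone does not set this list apart. Those that rose were Nkg7 (7.38 to 8.17), Gzma (6.30 to 7.15), Ccl5 (8.19 to 8.81), Klrd1, Il2rb and Zap70. The narrower range of values in the replicate 2 arrays was argued against as the source, since 9 of the 26 members of the whole list rose when the replicate 2 arrays of both genotypes were left out. RNA of NK cells in the DKO sorts stays open. Of 28 NK markers outside the fixed lists, 21 had a WT mean above 5.68. Some of these, such as Cd160 (5.77) and Ifng (5.81), still lay where signal cannot be told from background. Of the 28, 4 rose (Serpinb6b, Il18rap, Ctsw and Klrc1) and 1 fell (AW112010). The p-values were 0.293 in fry (directional), 0.038 in camera and 0.55 there with an estimated correlation. The counts of 4 risen and 1 fallen move with single arrays. In limma, 1 rose without WT replicate 1, WT replicate 3 or DKO replicate 1, and 6 without DKO replicate 3. Without WT replicate 2 or in replicates 1 and 3 only, 9 rose. None fell without WT replicate 3, DKO replicate 1 or DKO replicate 3. With all arrays, 10 of the 28 had an unadjusted p under 0.05 in limma. A rise of these genes within the B-lineage cells of DKO mice is a hypothesis that these data could not separate from such RNA.

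Of 29 genes of G2/M and mitosis 22 fell, while of 33 genes of DNA replication 9 rose and 1 fell (fry FDR 0.40; camera adjusted p = 0.83 with an estimated correlation), with a gap of 0.67 between the medians of the lists on the log2 scale. A trend of the difference with array brightness was argued against: among 10000 pairs of random lists matched on mean level, the central 95% of gaps reached from -0.22 to 0.19. The gap was 0.62 in replicates 1 and 3, which argues against the replicate 2 arrays as the source of the gap, though not of the replication list's call, which was lost there (adjusted p = 0.055, median 0.14 against 0.20, 4 members fallen). That call was also lost without WT replicate 2, DKO replicate 1 or DKO replicate 3 (0.40, 0.080 and 0.078) and with the dimmest genes dropped (0.14). It was kept in camera without WT replicate 1, WT replicate 3 or DKO replicate 2 (adjusted p of 0.0032, 0.0028 and 0.0050). With the replicate number as a block 14 members rose and 4 fell (0.0064), and with a term for replicate 2 16 rose and 5 fell (0.0057). A rise of replication genes as a group therefore stays open. An effect of the genotype on the distribution of cells over the cycle, or on the transcription of these genes at a given phase, may account for the gap, and no measure of cell-cycle phase was available.

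Of 28 early B-cell genes, 23 fell. A lower share of B-lineage cells in the DKO sorts would, if it acted alone, lower all B-lineage-restricted genes by a like amount. The SD of the log2 differences of 13 genes taken as such was 0.42 against a mean SE of 0.11. Igll1 (-0.21, but -0.37 without WT replicate 2), Pax5 (-0.40) and Ebf1 (-0.49) lay far from Vpreb3 (-1.51). That all 13 are restricted to the B lineage was assumed. If so, this spread argues against a lower share as the only source, and a lower share beside other changes was not excluded. At least 21 members fell under either other scaling, so the pattern did not hang on the choice among these. Median centring and another quantile normalization moved the median difference of all genes by only -0.021 and 0.016. They could hardly have undone these falls, so scaling in general was not tested as a source. A shift of the DKO sorts along B-cell development, which would move these genes unequally, was not tested. An effect of the loss of HDAC1 and HDAC2 on these genes may account for the pattern and stays a hypothesis.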

How the results depend on the processing

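The comparisons on replicates 1 and 3 only, with a term for replicate 2 and without Flt3 and Ptprf were chosen after the data were seen. Over the settings tried, 3669 changed genes became 2696 (median centring) to 5475 (term for replicate 2), and 2572 to 4004 when single arrays were left out. Beyond 1.5 times the reported count lay the genes lower in DKO (1446) at 2260 after another quantile normalization and 2213 with a term for replicate 2. So did the genes higher in DKO (2223) at 1465 after median centring and 1448 without DKO replicate 1. When single arrays were left out, the genes higher in DKO ranged from 1448 to 2658. With an estimated correlation 0 of the 7 lists passed. That fit differed from the main one only in the correlation, estimated at 0.039 to 0.71 for these lists against the preset 0.01. In fry, 2 of the 7 did not pass and 2 others did. The cause was not tested for the moved gene counts or for the differences in fry. Replicate numbers as a whole did not pair the arrays, but the replicate 2 arrays of both genotypes shared a deviation. Deviations of same-numbered arrays correlated across genes at 0.20, 0.54 and 0.043 for replicates 1, 2 and 3, and 0.54 was the highest of all pairs. WT replicate 1 correlated better with DKO replicate 3 (0.50) than with DKO replicate 1. Deviations cancel within a genotype, so these correlations are not independent of each other. With the replicate number as a block, 5004 genes changed (3019 higher, 1985 lower) and 8 lists passed, the T, NK and innate lymphoid list among them (adjusted p = 0.030). No called gene or list reversed. Of the values of named genes under alternatives, 2519 stayed on the same side of the threshold, 68 passed it newly and 107 no longer passed; of those of lists, 335, 19 and 21. Uncalled values changed sign 15 times for genes and 13 times for lists, with no call in either. Signal over background limits the lowest levels, where 0.913% of genes passed, against 27.2% of the others.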

Other observations

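The test of neighbouring genes was chosen only after the result was seen. Beyond the lists of the report, Myc and genes of ribosome biogenesis, glycolysis, the lysosome and end joining were looked at, all picked after single members had been seen. Myc, a transcription factor of growth and proliferation, rose 2.45-fold, from 9.36 ± 0.26 to 10.66 ± 0.17 (SD, n = 3 each), with an adjusted p of 1.96e-04 in limma. Of 29 measured genes of ribosome biogenesis, 23 rose and 0 fell, with 27 at an unadjusted p under 0.05 in limma and a median log2 difference of 0.60. Rrp9 rose 2.22-fold, Polr1b, of RNA polymerase I, 1.93-fold and Rrp12 1.93-fold, while the abundant nucleolar genes Ncl and Npm1 had differences of 0.17 and 0.28 without a call. The list moved up in fry (directional p = 0.0049) and in camera (2.01e-17, but p = 0.10 with an estimated correlation), and 19 to 27 members rose under other scalings. A raised output of Myc is a candidate explanation for this rise, and its protein was not measured.

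Of 13 genes of glycolysis besides Hk2 (3.01-fold higher) and Aldoa (3.03-fold higher), 8 rose and 0 fell, with 10 at an unadjusted p under 0.05 in limma and a median of 0.56. Pfkm, a phosphofructokinase gene, rose 1.97-fold and Pfkp 1.96-fold. Fry gave a directional p of 0.017 and camera one of 4.43e-05 (p = 0.17 with an estimated correlation). Without DKO replicate 1, 4 members rose, and without WT replicate 3 or DKO replicate 3, 5 did. After median centring 4 rose, and 1 fell without WT replicate 2 and in replicates 1 and 3 only. Slc16a1, a lactate transporter gene, had a log2 difference of -0.25 without a call. Of 20 lysosomal genes besides Ctsl, 13 rose and 0 fell, with 17 at an unadjusted p under 0.05 in limma and a median of 0.46. Ctsz rose 2.07-fold, Gaa 1.79-fold and Ctsd 1.78-fold. Fry gave a directional p of 0.011 and camera one of 1.02e-09 (p = 0.15 with an estimated correlation), and 8 members rose after median centring. Psap had a difference of -0.061 without a call.

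Lig4, the ligase gene of non-homologous end joining, fell 2.77-fold, with an adjusted p of 7.04e-06. Of 12 other end-joining genes, Xrcc6 (1.51-fold), Xrcc4 (1.37-fold) and Rad50 (1.29-fold) fell and Trp53bp1 rose 1.38-fold. Fry gave a directional p of 0.131 and camera one of 0.31, so a common shift of the list was not shown.

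A chromosome segment of other origin carried with the targeted genes was tested through their neighbours. Of the 60 tested genes nearest to Hdac1 and Hdac2, 15 on each side of each, 11 changed (18.3%), against 19.4% of the other genes, with a one-sided p of 0.63 in Fisher's exact test and an upper 95% bound of 1.83 for the odds ratio. This argues against a raised share of changed genes among these 60 neighbours. Genes farther from Hdac1 and Hdac2, and segments elsewhere in the genome, were not tested.

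The genotype comparison called 3669 genes, which 1 of the 10 divisions of the arrays reached, the real one itself, and the highest count of the others was 0. The other divisions mix the genotypes on both sides, so the genotype difference widens the spread within their groups. Their 0 therefore does not show how many genes chance would call. Part of that difference also stays between their groups, so their list counts are not free of it. In camera, 7 lists passed in the real division, 8 of the 10 divisions gave as many, and the highest of the others was 12, when WT replicates 1 and 3 and DKO replicate 3 stood against WT replicate 2 and DKO replicates 1 and 2. That division puts both replicate 2 arrays on one side, and without the replicate 2 arrays 7 lists passed for the genotypes, with the T, NK and innate lymphoid list (adjusted p = 0.026) in place of the replication list (0.055). With 10 divisions the share cannot lie under 0.05. In the principal components of the values, the first (64.7% of the variance) separated the genotypes and the second (19%) the replicate 2 arrays of both.

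With the authors' scaling, rises outnumbered falls in the 4th to 9th deciles of genes by level and not in the highest. In the 6th decile 394 genes were higher and 145 lower in DKO, in the 8th 455 and 294, in the 9th 401 and 298, and in the highest 293 and 344. The excess depended on the scaling: of all changed genes 60.6% were higher, against 53.1% after another quantile normalization and 54.3% after median centring, and the deciles were not counted under those.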
